A study of Mus musculus with 2 samples.

How the data were processed

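Chromatin immunoprecipitation sequencing (ChIP-seq) for dimethylated lysine 4 of histone H3 (H3K4me2), a mark of promoters and enhancers, was done on heart tissue of mouse embryos of 12.5 days, strain B6NCrl. Embryos of both sexes were pooled. There was 1 group with 2 biological replicates, each from its own biosample per the labels, with library fragments of 300 to 500 bp. Input controls belong to the study but are not analysed here. The labels give no second condition, so no contrast between conditions was possible.

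The 4 deposited peak lists were used, all on mouse build mm10 per the labels. The notes deposited with them say that each replicate's list was made from that replicate's alignments and 1 control alignment. The pooled list was made from both replicates' alignments and 2 control alignments, and the replicated list from the pooled list and both replicates' lists. The aligner, the peak caller, their versions and the peak thresholds are not given in the sources used here. Each peak carries a deposited peak signal value that is never negative and whose exact definition the deposited notes do not state. Each peak also carries a deposited −log10 q-value. Both are the authors' own values for the peak and were used to rank, filter or describe peaks within a list, and the signal value also to correlate the replicates across peaks. The plan had called the signal value fold enrichment, so it was compared between replicates by rank, with Pearson's r of log2 values as an alternative. The lists give no read counts, so the depth per sample is unknown, no interval over reads can be given, and the 95% Wilson intervals on shares cover counting error over peaks only.

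Genes were taken from GENCODE mouse release 21, and sequence from GRCm38, the same build as mm10. Protein-coding genes on chromosomes 1 to 19, X and Y were used, keeping the first entry of each symbol. Leaving out 27 further entries of repeated symbols, with their transcript starts, left 21911 genes with 93444 transcript starts. A gene had a TSS (transcription start site) peak when at least 1 bp of a peak lay within 1000 bp of any of its transcript starts. Breadth was the number of bases covered by peaks within 5000 bp of the transcript start with most covered bases, so at most 10001. Distal peaks had no base within 2500 bp of a protein-coding transcript start, and were given to the gene of the nearest start if it lay at most 100000 bp away. Domains were peaks merged over gaps of up to 1000 bp. Coordinates are 1-based.

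Overlap between lists needed at least 1 bp and was set beside 100 random placements of peaks within chromosomes (bedtools 2.31.1), which allow a one-sided permutation p of 0.0099 at the least, or 0.0198 two-sided. The 23 gene lists and their tests were fixed before the data were examined. So were the processing alternatives, except CpG matching of TSS peak shares, replicated peaks that overlap a peak of each replicate, merged distal peaks, rearranged consensus sequences and the direct comparison of cardiac with neural transcription factors, which were chosen after the data were seen. All genes on the lists but Ahsp matched the annotation. TSS peak shares were compared with those of all other protein-coding genes by two-sided Fisher's exact tests. Breadth was compared over members with a TSS peak, in the 20 lists with at least 5 such members, and distal peak numbers over all members. Both used two-sided permutation tests with 100000 random lists of the same size, whose smallest p is 2.0e-05. Benjamini-Hochberg adjustment was over the lists, with calls at an adjusted p below 0.05. Genes are not independent replicates, and neighbouring genes can share a peak, so these p-values describe the lists and not animals.

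For sequence content, 10 consensus sequences were searched on both strands of distal peaks and in equally wide sequences 5000 bp to the side that overlapped no pooled peak, with 1 free flank drawn at random per peak. The POU5F1-SOX2 consensus was allowed 1 mismatch. Discordant pairs were compared by an exact two-sided sign test, adjusted over the 10 sequences. Promoter CpG content was the number of CpG dinucleotides within 500 bp of the gene's transcript start with most covered bases. It therefore depends on where the peaks lie. Gene territory was the length of chromosome closer to the gene's transcript starts than to those of other genes. Random lists were matched on CpG content or territory by decile over all protein-coding genes.

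Genes are named by a rule fixed beforehand. Per list it takes up to 4 members with most covered bases and up to 2 members without a TSS peak. Across the genome it takes the 10 genes with the widest domains at a TSS, the 10 with most distal peaks, and the 5 strongest replicated peaks outside TSS windows with their nearest genes. Other named genes are said to be chosen after their values were seen.

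Alternatives were each replicate's own list in place of the replicated list (written as leaving out the other replicate), the pooled list, a −log10 q of at least 5, stricter overlap, other windows and distances, the gene's 5′ end alone, other backgrounds, and matched random lists or flanks. The tests were checked on simulated data. Over 21911 genes whose values had been shuffled between genes, with 2000 random lists, 10 of 10 planted lists of 30 genes were recovered for the TSS peak share when every member was given a peak, for breadth when covered bases were doubled, and for distal peaks when 3 were added per member. Of the 30 lists without a planted change, 0, 1 and 1 were called. Both planted sequences were recovered, with 0 of 8 others called. The simulated peaks and flanks had the same base composition, so that check did not cover a GC difference between them. Overlap and distance functions gave 0 mismatches in 5294 comparisons with direct counting. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and samtools 1.23.1 were used.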

Results

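H3K4me2 was mapped in the hearts of mouse embryos of 12.5 days, in 2 biological replicates of 1 group. The data are peak lists on build mm10, with 66118 peaks in replicate 1 and 68694 in replicate 2, or 67406 ± 1822 (SD, n = 2). The replicates' peaks covered 57.8 ± 0.789 Mb (SD, n = 2) and had a median width of 499.5 ± 6.36 bp. The pooled list held 74146 peaks over 66.5 Mb, and the replicated list, the main list below, held 53949 peaks over 61.5 Mb with a median width of 777 bp. Sequencing depth is unknown, since the lists give no read counts.

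In embryonic heart, H3K4me2 was concentrated at promoters. Of the replicated peaks on chromosomes 1 to 19, X and Y, 19926 (36.9%) lay within 1000 bp of the TSS of a protein-coding gene, against 5.87% for randomly placed peaks (permutation p = 0.0198, the smallest that 100 placements give). The replicates' own lists had 33.6 ± 1.04% of peaks there (SD, n = 2). TSS peaks were wide and strong, with a median width of 1673 bp and a median peak signal value of 26.2. Intronic peaks (28.9% of the list, 30.1% at random) had medians of 529 bp and 4.53. Intergenic peaks made up 28.2% of the list against 57.0% at random.

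The design's comparison between samples is that of the biological replicates. Of replicate 1 peaks, 81.5% overlapped a replicate 2 peak (Wilson 95% interval 81.2 to 81.8%), against 4.76% for random placements. Of replicate 2 peaks, 78.5% overlapped a replicate 1 peak (78.1 to 78.8%), against 4.58% at random. Both had a permutation p of 0.0099, the smallest that 100 placements give. With peaks split by signal value into 10 groups of equal size, every peak in the top 3 groups had a partner in the other replicate, whereas in the lowest group 50.3% of replicate 1 peaks and 41.4% of replicate 2 peaks did. Unshared peaks were narrow, with median widths of 220 bp and 227 bp, and held 5.31% and 6.57% of the covered bases. Across the 48933 replicated peaks with a peak in both replicates, Spearman's rho of the signal values was 0.905. That is a correlation across peaks, which are not independent replicates.

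**Figure D1:**
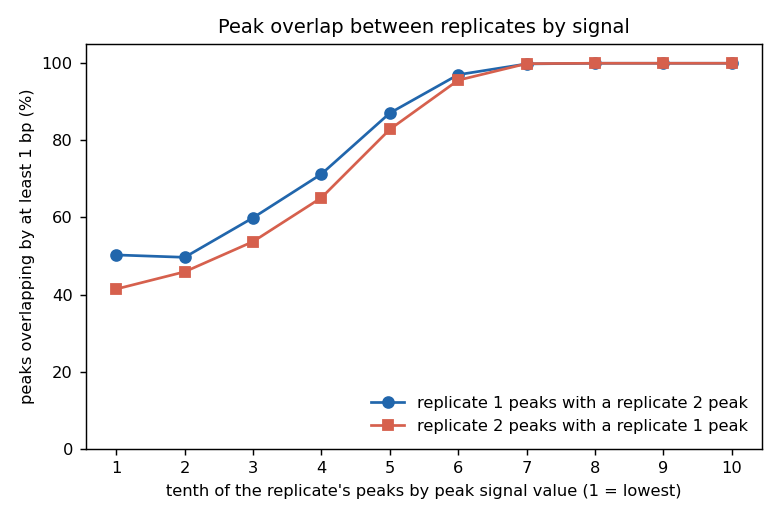
Share of each replicate's peaks (percent, vertical axis) that overlapped a peak of the other replicate by at least 1 bp, in 10 groups of equal size by peak signal value (horizontal axis, 1 is lowest). Circles are replicate 1 and squares replicate 2; both lines reach 100% in the top 3 groups, from 50.3% and 41.4% in the lowest.

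All 53949 replicated peaks were also in the pooled list, so 72.8% of pooled peaks were kept. The 20197 pooled peaks not kept were weak, with a median signal value of 2.75 against 7.36 for kept peaks, and 10.4% of them lay at a TSS against 36.9%. Being in the replicated list did not require a peak in each replicate's own list. On the main chromosomes 5003 replicated peaks (9.28%) had no overlapping peak in at least 1 of those lists, and 178 pooled peaks with a peak in both were left out.

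Protein-coding genes were mostly marked: 15231 of 21911 (69.5%) had a TSS peak, against 2949 on average for randomly placed peaks. The replicates' own lists marked 15288.5 ± 21.9 genes (SD, n = 2), and 15150 genes were marked in both. Genes of the heart's own cell types were marked nearly throughout. TSS peaks were present at 40 of 40 cardiac transcription factor genes, 34 of 34 endocardial and endothelial genes, 32 of 32 valve and cushion mesenchyme genes and 34 of 34 genes of heart developmental signalling. They were also present at 34 of 36 sarcomere and contractile genes, where Myom2 and Xirp2 had none, and at 32 of 33 cardiac ion channel and calcium handling genes, where Sln, a regulator of the calcium pump, had none. Smooth muscle and neural crest genes had a TSS peak in 21 of 22, without one at Plp1. Each of these 7 lists lay above the share of other genes (Fisher's exact test, adjusted p between 3.57e-06 and 0.00626). The epicardium list, with 18 of 21 genes, did not differ (Fisher's exact test, adjusted p = 0.185), and its genes without a TSS peak were Msln, Muc16 and Upk3b, the last named after its value was seen. Random lists matched on promoter CpG content, chosen after the data were seen, narrowed the excess of the 7 lists, except for sarcomere genes. Their shares were 90.7% for cardiac transcription factors, 88.4% for signalling, 82.2% for valve, 81.1% for endothelial and 49.4% for sarcomere genes. Each of the 7 lists still lay above its matched lists (adjusted permutation p at most 0.0104).

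Several lists of genes of other tissues were marked less often than other genes, but not all. Only 2 of 24 macrophage and leukocyte genes had a TSS peak, Cd14 and Coro1a, and Adgre1 and Aif1 were among those without (Fisher's exact test, adjusted p = 3.48e-09). Of 32 hepatocyte genes, 4 had one, Apoh, Vtn, Rbp4 and Ttr, while Afp and Ahsg did not (Fisher's exact test, adjusted p = 2.37e-10). Skeletal muscle genes had one in 11 of 28 (exact test, adjusted p = 0.002), and the call was lost in the pooled list (adjusted p = 0.0786). Pluripotency and germ line genes had one in 10 of 32 (exact test, adjusted p = 2.35e-05). Receptor genes were almost bare, with 6 of 1134 olfactory receptors (0.529%, against 73.3% of other genes) and 1 of 328 vomeronasal receptors, Vmn1r4 (exact test, adjusted p = 1.86e-168). Their promoters hold few CpG. Random lists matched on CpG content, chosen after the data were seen, had shares of 7.72% and 6.71%. Those were still above the receptors' shares (adjusted permutation p = 9.2e-05 for both). The matched lists were drawn from all genes, receptors included, so these shares do not give that of other genes with few CpG. Matched lists for the macrophage and hepatocyte genes had 41.9% and 39.3%, against 69.6% of all other genes. The macrophage and hepatocyte lists stayed below those shares (adjusted permutation p = 0.000747 for both). By contrast, 42 of 44 neural transcription factor genes had a TSS peak (exact test, adjusted p = 8.53e-05), without one at Neurod4 and Phox2b. Hox genes of groups 1 to 6 had one in 18 of 18 (exact test, adjusted p = 0.00419), a call lost with the 5′ end alone (adjusted p = 0.18). Housekeeping lists were high as well, at 36 of 36 ribosomal protein genes (exact test, adjusted p = 1.42e-05), 32 of 32 cell cycle genes (adjusted p = 3.75e-05) and 31 of 32 oxidative phosphorylation genes (adjusted p = 0.000295), where Atp5o had none. Atp5o has a single annotated transcript start at the end of its gene model on chromosome 16 (91684398 to 91926982), so its absence depends on that annotation, and 2319 bases within 5000 bp of that start were covered.

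Across the 23 lists, 12 had a higher share than other genes, 6 a lower share and 5 were not called. The uncalled lists were epicardium, erythroid (15 of 23, without Alas2 and Epb42 among others), neuronal function (24 of 30, without Dcx and Slc17a6 among others), lung and foregut (18 of 23) and Hox groups 9 to 13 (13 of 16, without Hoxc11 and Hoxc12 among others). Against random lists matched on promoter CpG content, a control chosen after the data were seen, the calls for neural transcription factors (95.5% against 91.6%), oxidative phosphorylation, Hox groups 1 to 6 and skeletal muscle were lost. Matching turned 2 directions: the erythroid list was then above its matched lists (65.2% against 38.8%, adjusted p = 0.00534) and Hox groups 9 to 13 below (81.2% against 97.9%, adjusted p = 0.0104; permutation tests). The pool for matching held all protein-coding genes, receptors included, which can lower the shares of matched lists with few CpG.

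**Figure D2:**
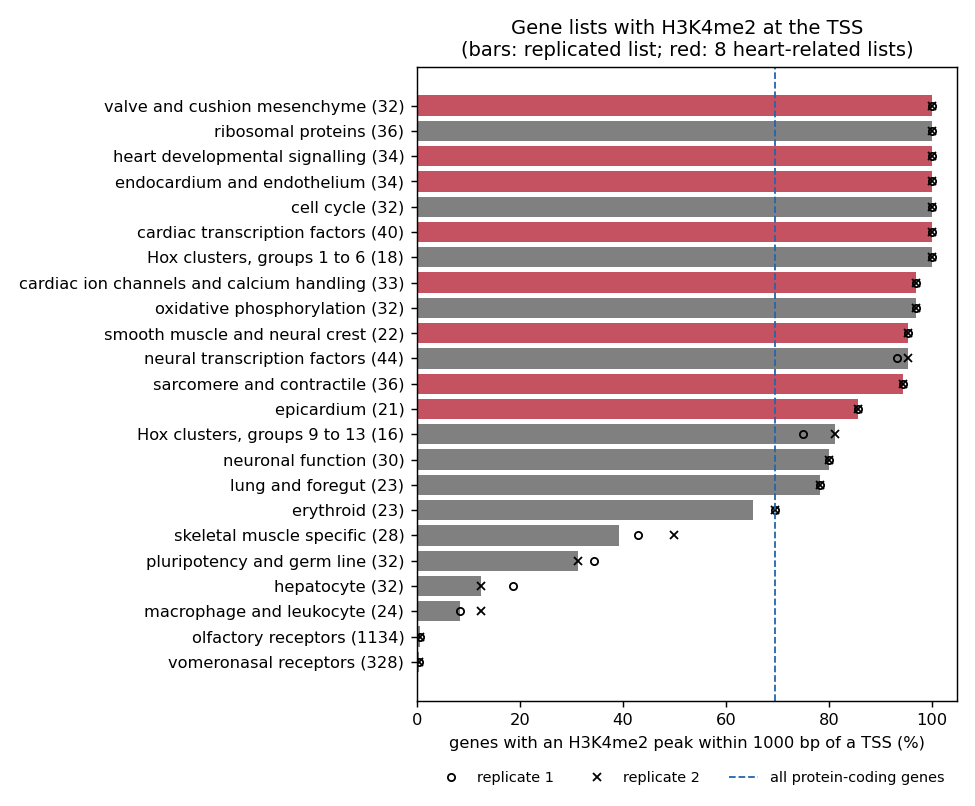
Share of genes with an H3K4me2 peak within 1000 bp of a TSS (percent, horizontal axis) for the 23 gene lists, with the number of genes in parentheses. Bars show the replicated list, with the 8 heart-related lists in red, circles and crosses show the replicates' own lists, and the dashed line marks the 69.5% of all protein-coding genes.

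Of the 8 heart-related lists, 7 carried broader H3K4me2 around the TSS than random lists of marked genes, and the epicardium list did not. The median over all genes with a TSS peak was 2586 covered bases within 5000 bp. Cardiac transcription factors had the highest median of the 20 lists tested, 7019 bases, against 2148.5 to 3133 in the central 95% of random lists. Their own replicate medians were 6791 ± 193 bases (SD, n = 2). Gata6 and Mef2d were covered over all 10001 bases of the window, and Tbx5, needed for chamber and septum formation, over 9943 bases (9826.5 ± 247 in the replicates' lists, SD, n = 2). Prdm16 had 9786 covered bases. Sarcomere genes followed with a median of 5806.5 bases, led by the myosin heavy chain gene Myh7 with 10001, Tpm1 with 9279, the cardiac actin gene Actc1 with 9237 and the troponin gene Tnnt2 with 8977.

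Genes of heart developmental signalling had a median of 5660.5 covered bases, led by Smad7 with 10001, Igf2 with 9635, Smad6 with 9050 and the retinoic acid receptor gene Rara with 8819. Valve and cushion mesenchyme genes had 5024.5, led by Pdgfra with 9567, Zeb2 with 8835, Vcan with 6773 and Prrx1 with 6645. Endocardial and endothelial genes had 4875.5, led by Fli1 with 8222, Nfatc1, a regulator of valve formation, with 8208, Tal1 with 8180 and Egfl7 with 7572. Ion channel and calcium handling genes had 4315.5, led by the gap junction gene Gja1 with 7638, Jph2 with 6705, Kcnh2 with 6567 and Cacna1c with 6389. Each of these 6 lists had an adjusted permutation p of 6.67e-05, from the smallest p that 100000 random lists give, and each was above random lists in both replicates' own lists. The epicardium list, with a median of 2377, was not called (adjusted permutation p = 0.553), although its gene Wt1, a regulator of the epicardium, had 9103 covered bases.

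Cell cycle genes were broader than random lists too, with a median of 3776.5 bases (adjusted permutation p = 0.00152), led by Ccnd2 with 8229 and Ccnd1 with 6709. Ribosomal protein genes had 3424 (adjusted permutation p = 0.0116), led by Rps11 with 7042 and Rps18 with 6777, and with the 5′ end alone that call was lost (0.0566). Oxidative phosphorylation genes, with a median of 2761 bases, were not called (adjusted permutation p = 0.553). Smooth muscle and neural crest genes had 3553 (adjusted permutation p = 0.0308), led by Tfap2a with 6677. That call was lost in replicate 2's own list (adjusted permutation p = 0.0667) and within 2000 bp or 10000 bp of the TSS (0.101 and 0.221). Neural transcription factors had a median of 3226.5 bases (adjusted permutation p = 0.0308), led by Sox3 with 6630, Pax6 with 5175 and Pou3f2 with 5037. In replicate 1's own list that call was lost (adjusted permutation p = 0.11), as it was within 2000 bp of the TSS (adjusted p = 0.961).

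Narrower than random lists were the marked genes of Hox groups 9 to 13 (median 1366 bases, adjusted p = 0.00147), of pluripotency and germ line (1115.5, adjusted p = 0.0005), of skeletal muscle (1723, adjusted p = 0.0348) and the 6 marked olfactory receptors (641, adjusted permutation p = 0.000114). The widest of these genes were Hoxd13 with 2664, Gdf9 with 2652, Mylpf with 4748 and Olfr94 with 1358 covered bases. With random lists matched on CpG content, and with the 5′ end alone, the skeletal muscle call was lost (adjusted permutation p = 0.323 and 0.339). Within 10000 bp the calls for Hox groups 9 to 13, pluripotency and germ line, and skeletal muscle were lost (adjusted permutation p = 0.175, 0.146 and 0.0859). Cardiac exceeded neural transcription factors directly, by 3792.5 bases in the median over 40 and 42 marked genes (two-sided permutation p = 1.0e-05, the smallest that 100000 permutations give), in a comparison chosen after the data were seen. At the starts with most covered bases both lists were CpG-rich, with medians of 63.5 and 66.5 CpG.

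**Figure D3:**
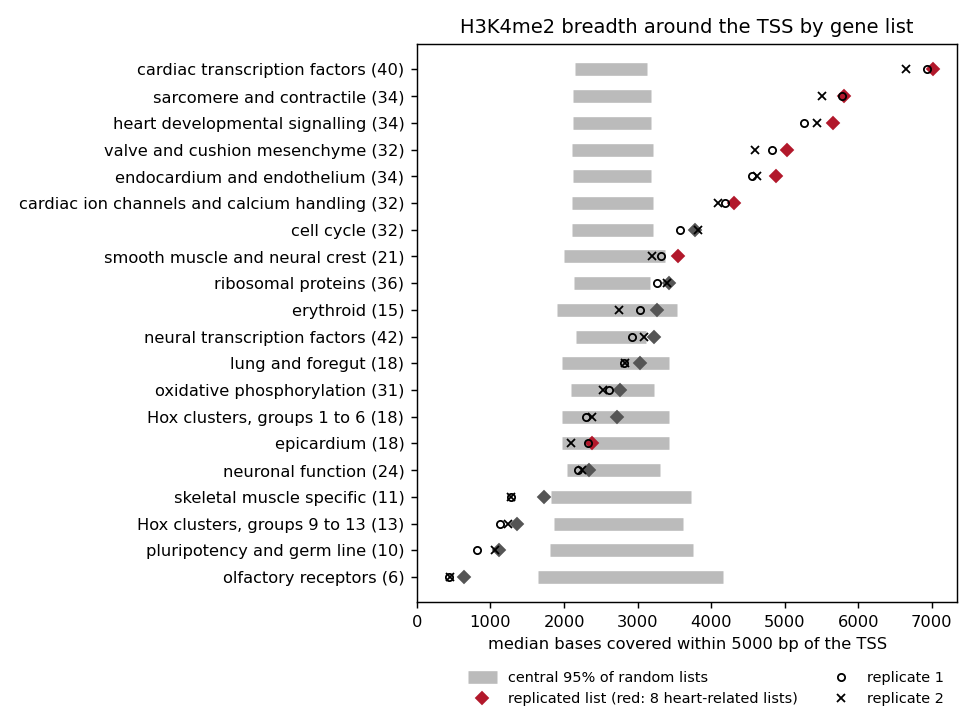
Median number of bases covered by H3K4me2 peaks within 5000 bp of the TSS (horizontal axis), over the members with a TSS peak (number in parentheses) of the 20 lists tested. Diamonds show the replicated list, with heart-related lists in red, circles and crosses show the replicates' own lists, and grey bars show the central 95% of random lists; cardiac transcription factors lie farthest right at 7019 bases.

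The widest H3K4me2 domain at a TSS belonged to Gata4 on chromosome 14 (63227841 to 63257181, 29341 bp), within the gene's own body. Next was Hand2 on chromosome 8 (57311684 to 57337919, 26236 bp), which encodes a factor for the right ventricle. Igf2r followed with 22800 bp, Myh7 with 19770 bp, Rbm38 with 19598 bp, Smad7 with 19515 bp, Nkx2-5, an early marker of the cardiac lineage, with 19296 bp on chromosome 17 (26835506 to 26854801) and Bahcc1 with 18337 bp. Aspdh and Josd2 shared a domain of 18204 bp. In all, 144 genes had a domain over 10 kb at a TSS. The Gata4 domain was made of 10 peaks in the replicated list, 13 in replicate 1 and 12 in replicate 2, the widest of 5988, 5976 and 5974 bp.

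**Figure D4:**
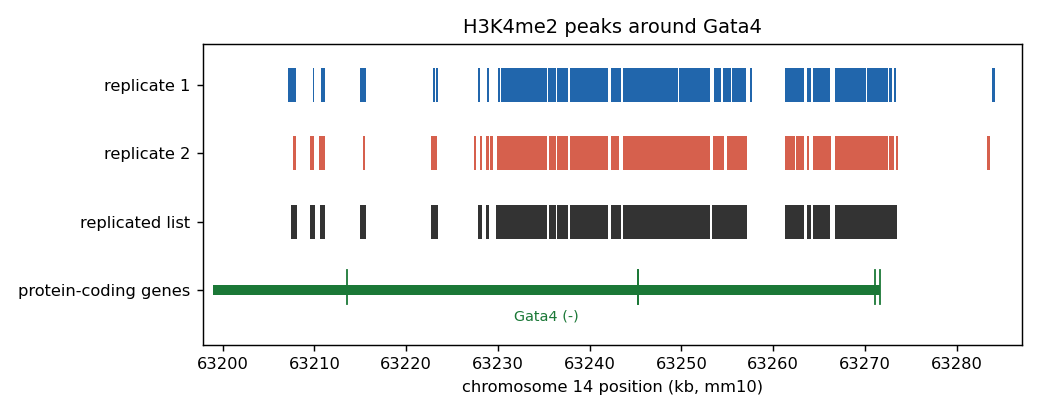
H3K4me2 peaks around Gata4 on chromosome 14 (horizontal axis, position in kb, mm10). Boxes are peaks of each replicate's own list and of the replicated list, drawn to scale, and the green bar is the gene with ticks at its annotated transcript starts; the domain of 29341 bp covers an internal start, and a separate block covers the 5′ end.

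Distal peaks, which include candidate enhancers, were more numerous around the genes of 8 lists than around random lists. Of the replicated peaks, 29441 were distal, and 8584 genes (39.2%) had at least 1 of the 25262 that could be given to a gene. Cardiac transcription factors had 6.90 distal peaks per gene, against 0.525 to 2.00 in the central 95% of random lists (adjusted permutation p = 7.67e-05). The replicates' own lists gave 9.15 ± 0.106 (SD, n = 2). Heart developmental signalling had 4.88 per gene, ion channels and calcium handling 4.52, and valve and cushion mesenchyme 4.31, each with the same adjusted p. Endocardium and endothelium had 3.82 and neural transcription factors 3.48 (adjusted permutation p = 0.000115 for both). Sarcomere genes had 2.72 (adjusted permutation p = 0.00547), and smooth muscle and neural crest genes 2.95 (adjusted p = 0.0176). The last call was lost against lists matched on gene territory (adjusted permutation p = 0.146) and against genes with a TSS peak (adjusted p = 0.0588). Below random lists were olfactory receptors with 0.0432 and vomeronasal receptors with 0.064 distal peaks per gene, although the 6 olfactory receptors with a TSS peak did not differ from other such genes (adjusted permutation p = 0.541). The other 13 lists were not called. Among the uncalled were epicardium with 1.33, cell cycle with 0.781 (1.25 and 1.28 in the replicates' own lists) and ribosomal proteins with 0.472. Cardiac exceeded neural transcription factors by 3.42 distal peaks per gene (permutation p = 0.00059), again in a comparison chosen after the data were seen.

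Across the genome, the most distal peaks belonged to Gse1 with 39 (56.5 ± 7.78 in the replicates' own lists, SD, n = 2), Nfib with 32, Bach2 with 31, and Casz1, a zinc finger gene needed in the developing heart, with 28. Kank1 also had 28, Smad7 had 27, Ank3 and Zmiz1 had 26 each, and Foxn3 and Rbm20, a splicing regulator of titin, had 25 each. All of these genes were in the 2 highest deciles of gene territory, and the counts were not adjusted for it. Among list genes already named, Zeb2 and Smad6 had 22 each, Prdm16 had 18, Hand2 17 and Gata4 16. The replicates' own lists often held more, with 32.5 ± 2.12 for Smad6, 29 ± 2.83 for Prdm16, 23 ± 2.83 for Gata4, 39.5 ± 6.36 for Zmiz1 and 36.5 ± 4.95 for Rbm20 (SD, n = 2). Pieces of a TSS domain over 2500 bp from a start count as distal peaks. Most of the 10 replicated peaks in the Gata4 domain were such pieces and are among its 16.

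**Figure D5:**
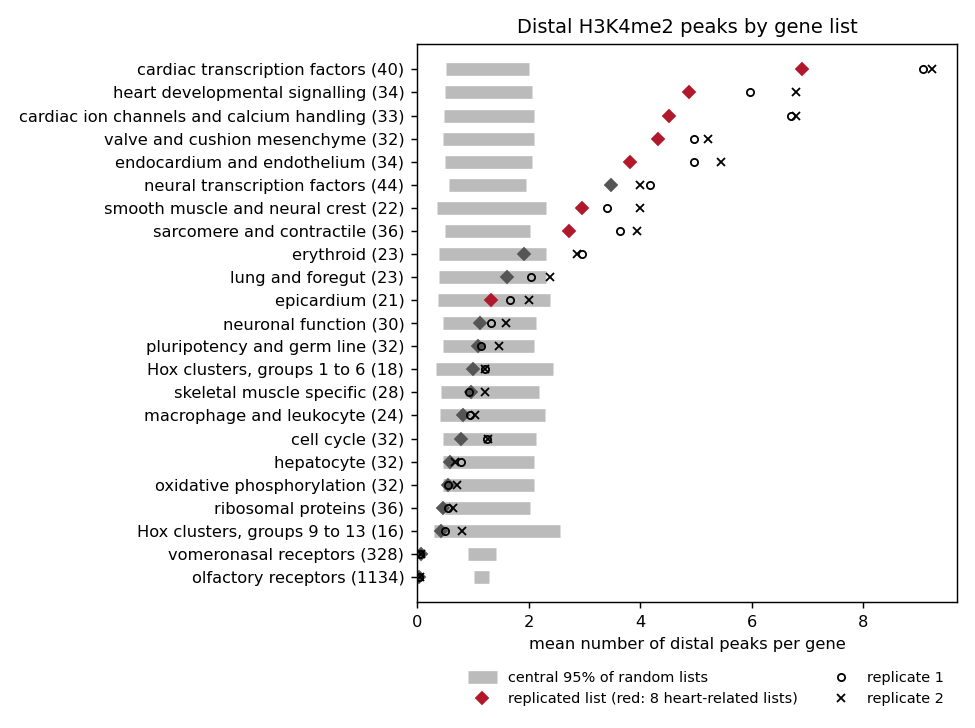
Mean number of distal H3K4me2 peaks per gene (horizontal axis) for the 23 gene lists, with the number of genes in parentheses. Diamonds show the replicated list, with heart-related lists in red, circles and crosses show the replicates' own lists, and grey bars show the central 95% of random lists drawn for the replicated list; cardiac transcription factors lie highest at 6.90.

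The 5 strongest replicated peaks outside TSS windows had nearest genes that are on none of the lists. The first, with a signal value of 70.4, lay on chromosome 4 (123685419 to 123687930), 1059 bp from a Macf1 TSS and so just outside the window. The others had nearest genes Apbb1ip (66.9, 28757 bp away), Zfp831 (62.7, in an intron, 29226 bp away), 1520401A03Rik (61.3, 5729 bp away) and Gm4952 (60.3, 2870 bp away, at the start of the noncoding transcript A330040F15Rik). These peaks were GC-rich, from 51.3% to 65.0%. All 5 peaks held GATA consensus matches, with 4 in the Macf1 peak and 3 in the 1520401A03Rik peak. The Apbb1ip and Gm4952 peaks held 1 each. These numbers were not compared with chance. The Zfp831 peak on chromosome 2 (174672760 to 174675016) held 3 such matches. The first, AGATAG at 174673136 to 174673141, stands in the sequence GTGGATGAAAAGATAGGTTCCTAGAT.

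Binding sequences of cardiac factors, with HNF1, POU5F1-SOX2 and ETS as planned controls, were compared between 28463 distal peaks and flanks of equal width. The TEAD consensus GGAATG occurred in 36.8% of peaks and 31.1% of flanks (exact sign test, adjusted p = 7.17e-50). Sites of the ETS control (ACCGGAAGT) occurred in 0.502% and 0.183% (exact sign test, adjusted p = 1.72e-10), so a planned control was called too. Fli1, among the broadly marked endothelial genes, encodes an ETS factor, so ETS is not a clear negative control in heart. GATA sites (WGATAR) were less frequent in peaks, at 64.1% against 66.3% (exact test, adjusted p = 3.08e-09), as were MEF2 sites (YTAWWWWTAR), at 9.61% against 11.5% (adjusted p = 7.6e-13). TBX, E-box, SRF and NKX2 sites, and HNF1 and POU5F1-SOX2 sites, were not called. HNF1 and POU5F1-SOX2 sites lay in only 7 and 6 of the peaks, so these controls could hardly have been called. TBX sites were called less frequent in peaks in replicate 1's own list (exact test, adjusted p = 0.0152), in the pooled list (0.0333), with a −log10 q of at least 5 (0.00372) and in peaks overlapping a peak of each replicate (0.00167). The last of these, chosen after the data were seen, also called NKX2 sites less frequent (0.0169). Peaks were richer in GC than flanks, at 50.9% against 44.7%. In the 5051 pairs matched on GC content, GATA sites were more frequent in peaks (67.8% against 61.8%, exact test, adjusted p = 5.34e-11). So were MEF2 sites (13.5% against 10.5%, exact test, adjusted p = 6.2e-06) and NKX2 sites (49.7% against 45.2%, adjusted p = 4.59e-06). TEAD sites stayed more frequent there (34.2% against 28.7%, exact test, adjusted p = 3.74e-09), and the call for ETS sites was lost (adjusted p = 0.383).

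H3K4me2 was unevenly spread over the chromosomes. Chromosome 11 had most covered bases for its length, 41.0 kb per Mb, and chromosome 14 fewest among the autosomes, 17.6 kb per Mb. The X chromosome had 8.40 kb per Mb, 0.337 of the autosome median of 24.9, and the replicates' own lists gave ratios of 0.345 and 0.331. Counted per protein-coding gene the order differed: chromosome 18 had most, 3.78 kb per gene, chromosome 7 fewest among the autosomes, 2.00, and chromosome 11 had 3.06, near the autosome median of 3.03. X then had 1.51 kb per gene, 0.5 of that median. On X, 53.7% of protein-coding genes had a TSS peak, against a median of 72.0% over the autosomes. The Y chromosome held 7 peaks in the pooled-sex tissue. Read depth and mappability by chromosome were not analysed here.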

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

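Replicated peaks on sequences not placed on a chromosome, which the report does not analyse, numbered 13 on 6 sequences, above the limit of 3 that a count of 0 allows. Their median signal value was 10.2, and each replicate's own list had 14 such peaks.

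Of the 29441 distal peaks, 1631 lay at the TSS of a noncoding gene, 5.54% against 1.11% for random placements. These genes are outside the report's comparisons. The 5 strongest such peaks, chosen after their values were seen, lay at A330040F15Rik, Gm49032, Gm36445, Gm43177 and Hand2os1, which neighbours Hand2.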

How the results depend on the processing

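Setting "replicated peaks overlapping a peak of each replicate", merging of distal peaks and CpG matching of TSS peak shares were chosen after the data were seen. The 6 heart lists stayed above random lists or other genes in all 10, 9 and 12 alternatives run for TSS peak share, breadth and distal peaks; these 6 were grouped after the main results were seen, and the smooth muscle and neural crest list, left out, lost calls in some. Of the alternatives for single list differences, 20 lost a call, 6 gained one and 4 changed sign with a call before or after. The other 652 changed no call, although some uncalled differences among them changed sign. Calls for higher values were gained for Hox groups 9 to 13 and neuronal function (TSS peak share, window of 2500 bp) and erythroid (distal peaks, territory). Calls for fewer distal peaks were gained for ribosomal proteins (pooled list and genes with a TSS peak) and oxidative phosphorylation (genes with a TSS peak). No paired analysis was possible because there is only 1 group. Depth is unknown.

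Each replicate's own list gave 57.2 to 58.4 Mb covered and 32.8 to 34.3% of peaks at a TSS. The pooled list gave 66.5 Mb and 29.7%. A −log10 q of at least 5 gave 59.4 Mb, 39.7% at a TSS, overlaps of 90.8% and 84.4% for replicate 1 and 2 peaks, and 95.4% of pooled peaks kept. Peaks overlapping each replicate gave 59.7 Mb, 39.7% at a TSS and 4 sequences lower in peaks. Overlap of 50% of the peak gave 74.9% and 70.9%, and of 50% of both peaks 65.4% and 62.9%. Pearson's r of log2 signal was 0.93. TSS windows of 500 and 2500 bp gave 33.9% and 45.4% at a TSS, and the 5′ end alone 28.1%. Narrower lists fell from 4 to 2 with the 5′ end alone, where skeletal muscle lost its call and olfactory receptors had too few marked members to be tested, and to 1, olfactory receptors, within 10000 bp.

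Flanks matched on GC gave 4 sequences higher and 0 lower in peaks, with peak minus flank shares turned to 6.04 (GATA), 2.95 (MEF2) and 4.51 (NKX2) percentage points. That matching also kept only 5051 of the 28463 pairs, so GC content and the choice of peaks changed together. CpG matching turned the TSS peak share differences to 26.4 (erythroid) and -16.7 (Hox groups 9 to 13) percentage points. Hox groups 1 to 6 turned to -607 bases within 2000 bp and to 0.667 distal peaks against lists matched on territory. The cause of these changes was not tested.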

Other observations

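Blood genes were marked in part. The strongest coverage among erythroid genes was at Nfe2 with 6775 bases within 5000 bp of the TSS, Zfpm1, a cofactor of GATA factors, with 6724, the anion exchanger gene Slc4a1 with 5568 and Epor with 4220. The list's median of 3264 bases was not called against random lists (adjusted permutation p = 0.196). Lung and foregut genes were led by Gata3 with 10001 covered bases, followed by Foxa2 with 4826. Among neuronal function genes, Gad1 had 5969 and Camk2a 4436 covered bases. In the anterior Hox genes, Hoxb2 had 6644 and Hoxa1 5216.

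The tests of explanations below were set down before their results were seen, except the CpG-matched comparison of neuronal genes. The 6 heart lists were grouped after the main results were seen, out of 8 heart-related lists. That left out epicardium, which had no excess, and smooth muscle and neural crest, whose excess in distal peaks and smaller excess in breadth were called as well.

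If CpG-rich promoters accounted for the breadth at heart genes, the excess would vanish against random lists matched on CpG content, but 6 of the 6 lists stayed above them (smallest excess 1544.5 bases). If the choice among several transcript starts did, it would vanish with the 5′ end alone, and again 6 of the 6 lists stayed above (smallest excess 1323 bases). There the excess shrank most for heart developmental signalling, from 3074.5 to 1773 bases, and for endocardium and endothelium, from 2288 to 1484.5. These values argue against the choice of start as the whole cause, though it may add to it. CpG was counted at the start with most covered bases, so the matching depended on breadth itself. That start held few CpG at some broad genes (Smad7 13, Tbx5 8) and many at others (Mef2d 111). The excess remained at a given CpG count of that start, but the matching cannot decide on CpG-rich promoters at a gene's other starts. A candidate explanation that stays open is that broad H3K4me2 marks genes active in the tissue's cells; the design has no second tissue, so no biological explanation was tested.

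Distal peaks at heart genes were weighed against random lists matched on gene territory, where 6 of the 6 lists stayed above (smallest excess 1.72 peaks per gene), while the smooth muscle and neural crest list, not among the 6, did not (adjusted permutation p = 0.146). With distal peaks up to 1000 bp apart counted once, which left 25734 of 29441, 6 of the 6 lists stayed above (smallest excess 1 peak per gene). The excess shrank in part, from 3.22 to 2.12 peaks for valve and cushion mesenchyme with matched territories, and from 1.61 to 1 for sarcomere genes with merging. Neither differences between deciles of territory nor splitting among distal peaks accounts for the whole excess of these 6 lists, though both may add to it. Size differences within a decile, as among the largest territories, were not controlled. Only distal peaks were merged with each other. Pieces of a TSS domain over 2500 bp from a start, as in the 29341 bp Gata4 domain, still counted as distal peaks. Splitting of such domains was therefore not tested, and neither was any biological explanation. Assignment to the nearest TSS is itself an assumption that stays open.

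Neural transcription factors had broader domains than random lists, but only just. CpG-rich promoters would bring the list within matched random lists, and it lay above them by 596 bases (permutation p = 0.0239). CpG was counted at the start with most covered bases, so the matching cannot decide on CpG content at other starts. Replicate 1's own list did not keep the call. Neurons in the dissected tissue would mark neuronal function genes with few promoter CpGs, and 11 of 17 such genes had a TSS peak against 40.3% of others (Fisher's exact p = 0.0483), which by the rule set beforehand favoured neurons. Against genes of the same CpG content (62.4%) no excess was left (permutation p = 1), so with 17 genes a contribution of neurons cannot be told apart from CpG content.

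A control for base composition, chosen after the data were seen, rearranged the letters of each consensus 20 times. Where the consensus held no CG, rearrangements with the letters CG were avoided. The ETS consensus (ACCGGAAGT) holds a CG, so its rearrangements had no such limit. Letters that stand for several bases, as in NKX2 (YAAGTG) and MEF2 (YTAWWWWTAR), were left free to match CG. The counts for ETS and for such sequences are thus not controlled for CpG content. For TEAD, 0 of 20 rearrangements had as large an excess in peaks as the 5.70 percentage points of the consensus. MEF2 and GATA had negative differences between peaks and flanks, -1.87 and -2.26 percentage points. Their rearrangements were mostly lower still (medians -9.83 and -8.49), with 0 of 20 as high for MEF2 and 1 of 20 for GATA. For ETS, 2 of 20 were as high as the consensus, and for NKX2 4 of 20. For SRF 1 of 20 were, for E-box 6 and for TBX 15. For HNF1 and POU5F1-SOX2, which few peaks held, 2 of 20 were.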
